A study of Anas platyrhynchos with 8 samples.

How the data were processed

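Abdominal fat was taken from ducks (Anas platyrhynchos) of an F2 population on day 42 after birth, frozen, extracted with Trizol and sequenced on an Illumina instrument, per the labels' protocols. The 8 libraries fall into 4 from ducks with a high abdominal fat rate (HF) and 4 from ducks with a low rate (LF). Groups and numbers were taken from the sample titles. The labels do not say whether a library comes from 1 bird or a pool, so p-values measure only the spread between these samples. Sex, batch and the strandedness of the libraries are not given in the sources used here, and reads of genes that overlap an antisense partner cannot be told apart.

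The authors deposited a table of mRNA transcripts and a table of lncRNA transcripts, each with estimated counts and FPKM per library, per the file headers. Each row is a transcript, with a RefSeq accession or an identifier of an assembled model (TCONS). The estimated counts are not whole numbers and sum to a different total in each library, so a quantifier had shared reads between transcripts before the authors deposited them. Bowtie2 2.2.8 and TopHat2 2.1.1 are named in the submitters' processing notes without a role. The genome build and the quantifier are not given in the sources used here. The deposited mRNA table also holds the authors' log2 fold change and an unadjusted p-value whose test is not named. That log2 value equals the log2 ratio of mean FPKM, with a mean of 0 replaced by 0.001, in all 48592 rows within a tolerance of 0.001. An additional column of the same table was not used here.

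The mRNA table had 48592 rows, of which 8688 were TCONS models and 10541 were at 0 in all libraries. The lncRNA table had 13220 rows, of which 6759 were at 0. Counts were rounded to whole numbers. The 2137 mRNA rows without a symbol held 0.839% to 0.965% of the counts. They were tested as transcripts and left out of sums per gene. Sums per gene used the symbol in the deposited table and gave 13213 symbols.

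The total estimated count per library in the mRNA table ranged from 12696240 to 30836178, and that of the lncRNA table from 92196 to 175194. Intervals and limits drawn from counts cover counting error only. Where a group was at 0, a fold was computed against 3 counts over the whole group and written as a lower bound. Where a group held 1 to 3 counts, the ratio has an exact 95% conditional binomial interval.

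The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling and filterByExpr, group as the only term and Benjamini-Hochberg adjustment within each class of transcript, at an adjusted p under 0.05. It was run on mRNA transcripts as deposited, on sums per gene, and on lncRNAs with scaling from both tables. A positive log2 fold change means higher in HF. Standard errors were derived from the fold change and its F statistic. Levels are CPM with TMM scaling, given as mean ± SD. Of 26 gene lists written before the data were examined, all had at least 3 measured members. They were tested on sums per gene with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists. At that setting 6 or more lists passed in 28 of 35 splits of the libraries into 4 and 4. Its p-values alone therefore do not support a list. Members past the threshold are counted over all genes tested. Counts adjusted over the list alone are given for some lists and named as such.

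The genes to be named were also set by a rule before the data were examined. It takes the 10 largest rises and 10 largest falls past the threshold among features with a symbol whose groups do not overlap, filled to 5 per direction by the smallest p where fewer pass. The same holds for lncRNAs with 5 per direction. Of each list it takes up to 4 members past the threshold, or the 2 with the smallest p where fewer than 2 pass. PPARG, FASN, LPL, PNPLA2, LIPE, FABP4, ADIPOQ, CD36, FOXO1 and FOXO3 were named whatever their result. Any other gene named in the text was chosen after its values were seen. The rule was applied to transcripts and again to sums per gene.

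Alternatives set beforehand were DESeq2's size factors, upper-quartile scaling, DESeq2 1.42.0, limma on log2(FPKM + 1) with a mean FPKM of at least 0.5, no low-count filter, a fold of at least 2, the replicate number as a block, 1 surrogate variable (sva 3.50.0), leaving out each library, summing per gene, lncRNA scaling from its own table, and for the lists an estimated correlation and fry. A covariate for the presence of W-described transcripts, the chromosome Z comparison and the KEGG pathways named in the deposited annotation (15 to 300 genes each) were added after seeing the data. The reference gene table used here is of the assembly IASCAAS_PekinDuck_T2T. It was used only to ask which symbols lie on chromosome Z, and no coordinates are given. It placed 9347 (88.9%) of the tested sums per gene. Of the 13220 lncRNA accessions, 9 matched it with their version and 2542 without it. Genes next to lncRNAs were not analysed here, since no lncRNA passed the test.

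The libraries were checked for repeated deposits: at most 0.494% of nonzero values were identical in any of 28 pairs. The tests were tested on simulated data drawn from the means and dispersions of the real libraries with 100 features changed 2-fold and 100 changed 4-fold. In sums per gene, edgeR recovered 49% of the 2-fold and 89% of the 4-fold changes, with 5.48% false calls. In transcripts it recovered 1% and 20%, and in lncRNAs 0% at both sizes. DESeq2 recovered 54% of the 4-fold changes in transcripts but 63.5% of its calls were false. In sums per gene 21.4% of its calls were false, and in lncRNAs 15.3%. The simulated lncRNAs were scaled from their own counts, and limma was given CPM in place of FPKM. Features were drawn independently with edgeR's dispersions. These rates therefore describe the simulations and may differ for the fits as run.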

Results

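Libraries of abdominal fat, 4 from ducks with a high (HF) and 4 from ducks with a low (LF) abdominal fat rate, were compared at day 42, to ask which mRNAs and lncRNAs differ with fat deposition. The mRNA table held 24416731, 13244545, 22360426 and 21791698 estimated counts in HF-1 to HF-4 and 12696240, 30836178, 21226969 and 25897206 in LF-1 to LF-4. The lncRNA table held between 0.556% and 0.874% of the counts of both tables together. Log2 CPM of different libraries correlated across genes with r from 0.949 to 0.974 within HF, 0.953 to 0.966 within LF and 0.935 to 0.966 between the groups. Genes are not independent replicates in these values.

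Summed per gene, the largest rises in HF past the threshold were in SHISA6, SCNN1A, ALPK3, OPRM1 and CNTN4. SCNN1A, the alpha subunit of the epithelial sodium channel, stood at 12.3 ± 3.93 CPM in HF and 0.550 ± 0.191 in LF (SD, n = 4 each), 22.2-fold higher in HF. SHISA6, a partner of glutamate receptors, was at 18.3 ± 12.3 against 0.484 ± 0.242 CPM. CNTN4, a neuronal adhesion molecule, was 7.49-fold and SLC2A9, a urate transporter, 5.98-fold higher. DPYD, the first enzyme of pyrimidine breakdown, rose 3.33-fold, from 21.0 ± 2.42 to 69.9 ± 10.9 CPM. ALPK3 rose 10.2-fold, the opioid receptor gene OPRM1 8.28-fold, DBNDD1 6.30-fold, FAM69B 3.93-fold and TMEM200A 3.65-fold. OPRM1 (3.29 ± 1.51 against 0.383 ± 0.193 CPM) and DBNDD1 (2.045 ± 0.896 against 0.308 ± 0.147) were low in both groups. The edgeR adjusted p was 0.00228 for SCNN1A, 0.00298 for DPYD and between 0.0105 and 0.0478 for the other 8.

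The largest falls in HF were in STC2, APELA, ZBTB16, CPLX2 and GADD45G. STC2, a stanniocalcin, was at 0.180 ± 0.0359 CPM in HF and 5.92 ± 3.38 in LF, 31.4-fold lower in HF. APELA, a ligand of the apelin receptor, stood at 5.08 ± 2.71 against 109 ± 114 CPM, and its LF mean rested partly on LF-4 at 280.1 CPM. The log2 fold change of APELA was -4.43 with all libraries and -3.35 without LF-4 (edgeR adjusted p = 0.0128). The transcription factor ZBTB16 was 10.1-fold lower, the prokineticin receptor PROKR1 7.02-fold, GADD45G 7.02-fold and CPLX2 7.52-fold. CPLX2 was low in both groups, at 0.154 ± 0.0438 CPM in HF and 1.17 ± 0.311 in LF. The noradrenaline transporter SLC6A2 fell 4.65-fold, IYD, which recovers iodide from iodotyrosines, 3.97-fold and RHPN2 3.89-fold. APOA1, the main protein of high-density lipoprotein, was at 2711 ± 1331 CPM in HF and 10312 ± 1536 in LF, 3.8-fold lower. Adjusted p by edgeR lay between 0.0105 for PROKR1 and 0.0419 for APOA1.

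**Figure D1:**
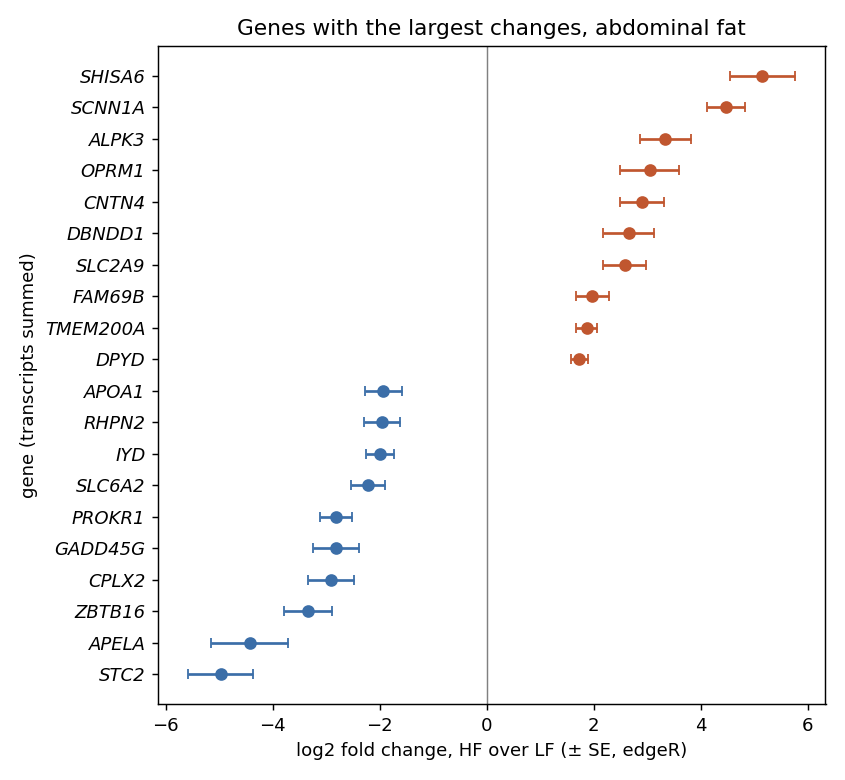
Log2 fold change of HF over LF for 20 genes past the threshold, the largest rises and the largest falls, transcripts summed per gene. Rises and falls were ranked separately. Points are edgeR estimates, bars are ± SE, 4 libraries per group, orange higher and blue lower in HF. Values run from -4.97 for STC2 to 5.16 for SHISA6.

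In all, 68 of 10511 sums per gene passed edgeR's test, 31 higher and 37 lower in HF, and 1576 had an unadjusted p under 0.05, where 526 are expected by chance. All 68 had groups that did not overlap, as did 9.19% of all genes tested and 2.86% by chance. The count was 2 without HF-1, 14 without HF-3, 6 without HF-4, 30 without LF-1 and 19 without LF-3, and SCNN1A and DPYD passed in all 8 such fits. SHISA6, TMEM200A and PROKR1 passed in 7, STC2 and ZBTB16 in 6, CNTN4, GADD45G and IYD in 5, ALPK3 in 4, SLC2A9, FAM69B, APELA, CPLX2 and SLC6A2 in 3, OPRM1, DBNDD1 and RHPN2 in 1 and APOA1 in 0. DESeq2 called 606 genes and a fit with a covariate for W-described transcripts 128, of which 26 were among the 68. Since LF-4 is the single LF library with those transcripts, that fit sets the HF libraries against LF-4 alone, which is assumed to vary like the others.

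Libraries differed in transcripts of the sex chromosomes, and sex is not in the labels. The 8 transcripts described as W-linked or Wpkci held 4226, 1818, 3410 and 2846 counts in HF-1 to HF-4 and 8, 7, 3 and 2861 in LF-1 to LF-4. Thus all HF libraries but only LF-4 of the LF libraries held them beyond 8 counts. HF against LF is therefore in part a contrast of W content, from which the gene results cannot be fully separated. Of 468 tested genes that lie on chromosome Z of the reference assembly IASCAAS_PekinDuck_T2T, 13 passed the threshold, against 47 of 8879 placed elsewhere (Fisher's exact test, two-sided, p = 6.26e-06). That test counts genes from the same libraries as independent, so its p does not measure the spread between samples. Of these 13, 12 were lower in HF: RPS23 (log2 fold change -1.33 ± 0.17, SE), RNF20, MTREX, BDP1, WDR70, GADD45G, PLPP1, JMY, KLF4, NDUFS4, IFT74 and MRPL50. HOMER1 was higher, by 1.47 ± 0.27. The median log2 fold change was -0.23 over genes on Z and 0.0045 over the others. Those named here beyond the rule were chosen after their values were seen.

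**Figure D2:**
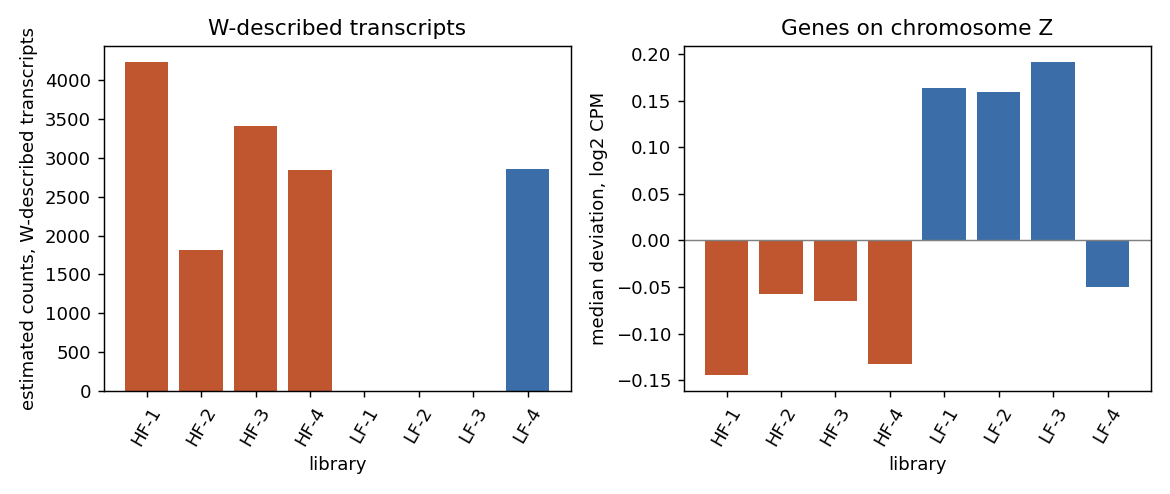
Left, estimated counts of the 8 W-described transcripts per library; right, the median deviation of 468 genes on Z from their mean over all libraries (log2 CPM), HF in orange and LF in blue. LF-4, with 2861 counts, and the HF libraries lie below 0 on the right (-0.0504 in LF-4), and LF-1 to LF-3 lie between 0.159 and 0.192.

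In the lists of fat synthesis and storage, the regulator INSIG1 and the droplet gene PLIN3 rose in HF. INSIG1, which holds the sterol regulator SREBP in the endoplasmic reticulum, was 2.48-fold higher (876 ± 173 against 353 ± 64.4 CPM, edgeR adjusted p = 0.0196). PLIN3, a lipid droplet coat protein, was 2.57-fold higher (1909 ± 536 against 744 ± 144 CPM, edgeR adjusted p = 0.0419). INSIG1 passed in 3 and PLIN3 in 1 of the 8 fits that left out a library. DGAT2, which makes triglyceride, stood at 1993 ± 599 against 408 ± 347 CPM and did not pass (edgeR adjusted p = 0.121), with LF-2 at 895.2 CPM. Its log2 fold change was 2.29, and 3.02 without LF-2, where it passed (adjusted p = 0.0444). Of 15 measured genes in the list of fatty acid and triglyceride synthesis, only 1, the regulator INSIG1, rose over all genes tested. Adjusted over the list alone 3 rose, and 11 were positive with a median of 0.31. The camera adjusted p of this list was 0.0108, and 0.716 with an estimated correlation. It was 0.064 without HF-3, where the median was 0.16, 0.0673 without LF-1 and 0.0677 with the W covariate, which sets HF against LF-4 alone. Among 17 genes of fatty acid uptake and lipid droplets the median was 0.22 (camera adjusted p = 0.228), and 0.096 without HF-3, with PLIN3 as the 1 that rose. VLDLR, also a member of the list of conserved Z-linked genes, had a log2 fold change of 0.78 ± 0.16 that did not pass. It passed without LF-1 (0.93, adjusted p = 0.0412).

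Cholesterol synthesis had the highest list median. Of its 16 measured members 15 were positive, 12 rose adjusted over the list alone and 0 over all genes tested. CYP51A1, a demethylase of lanosterol, stood at 25.8 ± 15.8 against 9.18 ± 2.31 CPM and the isomerase IDI1 at 34.3 ± 13.8 against 17.9 ± 1.37, with edgeR adjusted p of 0.111 and 0.117. The list median was 0.82 (camera adjusted p = 2.07e-06, and adjusted p = 0.716 with an estimated correlation). Without HF-3 the median was 0.51, and CYP51A1 was at a log2 fold change of 0.97 instead of 1.49 and IDI1 at 0.62 instead of 0.94.

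**Figure D3:**
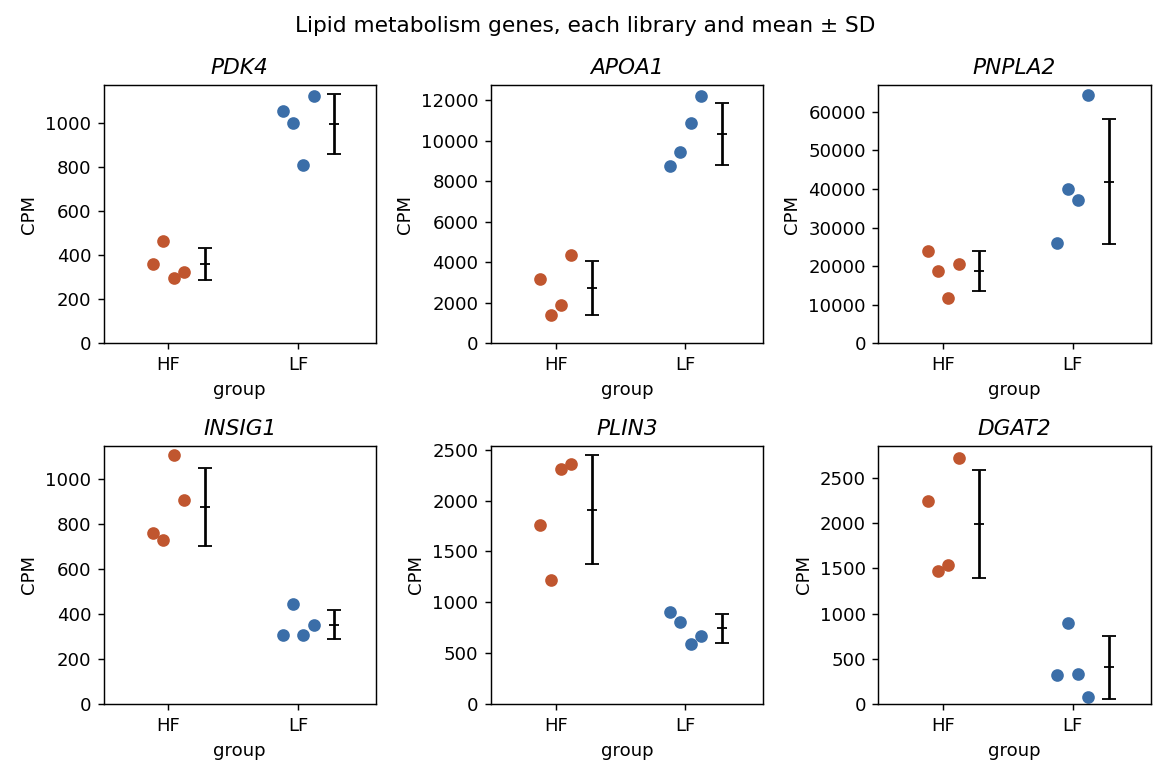
CPM of 6 genes in each library (points) with the group mean ± SD beside them (bars), n = 4 per group, linear axes from 0. PDK4, APOA1 and PNPLA2 are lower in HF and INSIG1, PLIN3 and DGAT2 higher, with no overlap between groups; PNPLA2 and DGAT2 did not pass the adjusted test.

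Among genes of fuel use and lipolysis, PDK4 and NDUFS4 fell in HF and no list passed. PDK4, a kinase that switches off pyruvate dehydrogenase, fell 2.76-fold (360 ± 73.3 against 995 ± 135 CPM, edgeR adjusted p = 0.0137). PNPLA2, adipose triglyceride lipase, was at 18728 ± 5155 CPM in HF and 41896 ± 16140 in LF, with no overlap, and did not pass (edgeR adjusted p = 0.144). PDK4 did not pass without HF-1 (adjusted p = 0.0623) or HF-4 (0.0651). GNAS was at -0.59 ± 0.14 on the log2 scale and did not pass. The lipolysis list of 12 measured genes had a median of 0.11 and a mean of -0.022 (camera adjusted p = 0.921), with a median of 0.012 without HF-1 and 0.050 without HF-4, and 2 members fell adjusted over the list alone. Fatty acid oxidation had a median of -0.034 over 16 genes (adjusted p = 0.547), which turned to 0.043 without HF-2, 0.014 without HF-3 and 0.021 without LF-2 and was -0.13 without HF-4, with ACAA2 at -0.44 ± 0.15 and SLC25A20 at -0.32 ± 0.12. Oxidative phosphorylation had -0.023 over 26 genes (adjusted p = 0.657), which turned to 0.068 without LF-2, 0.044 without HF-2 and 0.019 without LF-4 and was -0.13 without LF-1 or LF-3. Of these, NDUFS4, on chromosome Z, fell, but among the fits that left out a library it passed only without LF-4. That fit cannot tell sex from fat group. NDUFB8 was at 0.42 ± 0.19. The glycolysis list, which holds PDK4, had a median of 0.23 and a mean of -0.058 over 14 genes (adjusted p = 0.348). The median was 0.15 without HF-4, and PFKM was at -2.04 ± 0.78, or -0.59 without LF-3.

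Of 23 insulin and FOXO signalling genes, 15 were negative, with a median of -0.16 (camera adjusted p = 0.0485, and adjusted p = 0.716 with an estimated correlation). IGFBP3, a carrier of insulin-like growth factors, fell 2.62-fold (24.0 ± 5.03 against 62.8 ± 14.7 CPM, edgeR adjusted p = 0.0208). IGFBP3 did not pass without HF-1, HF-3, HF-4 or LF-3 (adjusted p from 0.0598 to 0.0951). PIK3R1, also a member of the list of conserved Z-linked genes, was at -0.82 ± 0.20 and did not pass. The camera adjusted p was 0.0952 without HF-1, 0.064 without HF-3, 0.234 with the W covariate (HF against LF-4 alone) and 0.0611 without LF-1, where the median was -0.082, and the median was -0.26 without HF-2 or LF-4. Adipogenic regulators and adipokines had a median of -0.18 over 21 genes (adjusted p = 0.292), -0.11 without LF-1 and -0.27 without LF-4, with CEBPD at -1.29 ± 0.30 and EBF1 at -0.32 ± 0.11, neither past the threshold.

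Among the adipocyte genes named beforehand none passed. The fatty acid transporter CD36 was at 3846 ± 513 against 5291 ± 607 CPM (edgeR adjusted p = 0.242), and FASN at 2380 ± 597 against 1640 ± 566 (adjusted p = 0.365). FOXO3 had a log2 fold change of -0.56 ± 0.25 and PPARG of -0.30 ± 0.21. FASN was at 0.54, or 0.81 without LF-2, and PPARG at -0.47 without LF-1 and -0.16 without LF-2. FABP4, FOXO1, LPL and ADIPOQ lay between -0.11 and -0.0066, with SE from 0.16 to 0.45. Their highest values leaving out a library were 0.018 for FABP4 (without HF-2), 0.055 for FOXO1 (HF-3), 0.21 for LPL (LF-2) and 0.46 for ADIPOQ (LF-3). LIPE was not measured under that symbol.

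Macrophage markers leaned higher in HF as a list. Of 15 measured, 14 were positive, 5 rose adjusted over the list alone and 0 over all genes tested, with a median of 0.59 (camera adjusted p = 0.00018, and adjusted p = 0.716 with an estimated correlation). The preset setting passed 6 or more lists in 28 of 35 splits of the libraries, so its p adds no support here. The complement gene C1QA was at 32.3 ± 10.2 against 17.3 ± 1.93 CPM and the transcription factor SPI1 at 47.2 ± 23.8 against 22.1 ± 2.96, and neither passed alone, though C1QA did without HF-2 (log2 fold change 1.08, adjusted p = 0.0366). SPI1 was at 1.10, or 0.69 without HF-3. Cell division genes had a median of 0.71 over 21 members, 20 positive and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.00135, and adjusted p = 0.823 with an estimated correlation). Without HF-3 that median was 0.25 (adjusted p = 0.142). MCM2 was at 0.70 ± 0.24 and PLK1 at 1.45 ± 0.58, or 0.74 without HF-3. Lymphocyte markers had a median of 0.26 over 11 genes (adjusted p = 0.0598), and passed without any one library other than HF-1 (adjusted p = 0.155) and LF-2 (adjusted p = 0.0677). Their median was 0.42 without HF-3 or LF-1 and 0.71 without LF-3. With all 8 libraries IKZF1 was at 0.87 ± 0.24 and JCHAIN at 1.05 ± 0.49, neither past the threshold. The interferon list had -0.053 over 17 genes (adjusted p = 0.921), from -0.18 without HF-2 to 0.058 without LF-3, with DTX3L at -0.25 ± 0.14 and IFI35 at 0.31 ± 0.18, or 0.13 without HF-4.

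Ribosomal protein genes were lower in HF, with 35 of 39 negative and a median of -0.34 (camera adjusted p = 2.65e-06, and adjusted p = 0.823 with an estimated correlation). RPS23, on chromosome Z, fell 2.52-fold and RPL27 was at -0.84 ± 0.19. RPS23 did not pass without HF-1, HF-3 or HF-4 (adjusted p from 0.0501 to 0.0644). Without LF-4 the list median was -0.14 (adjusted p = 0.0101). The 13 mitochondrial genome transcripts were all negative, with a median of -0.61 (adjusted p = 0.053). Without LF-1 the median turned to 0.052 (adjusted p = 0.997), and without HF-2, HF-4, LF-2, LF-3 or LF-4 the list passed, with medians from -0.82 to -0.64. They took 4.41% of counts in LF-1 against 1.45% to 2.16% in the other libraries. MT-ND1 was at -0.61 ± 0.29, or -0.28 without LF-1, and MT-ND6 at -0.32 ± 0.18. Handling genes had a median of -0.17 over 20 members (camera adjusted p = 0.187). They passed without HF-2 (median -0.37) or LF-4 (-0.30), and the median was -0.043 without HF-1 and -0.11 without LF-1. Of these genes, HSPA2 was at 0.87 ± 0.20 and KLF4, on chromosome Z, fell 2.16-fold. Among the fits that left out a library KLF4 passed only without LF-4, where sex cannot be told apart from fat group.

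Structural and other cell types gave no list past the threshold with all 8 libraries. Collagens and matrix had a median of 0.31 over 25 genes (camera adjusted p = 0.0598), with FN1 at 0.62 ± 0.28 and TIMP3 at -0.48 ± 0.19. This list passed without HF-4, LF-1 or LF-2, and its median was 0.49 without LF-2, 0.19 without HF-3 and 0.11 without LF-4. Stromal progenitor markers had 0.29 over 14 (adjusted p = 0.16), with CD34 at 1.11 ± 0.31 and FBLN1 at -0.63 ± 0.16, and passed without HF-4 or LF-2, while the median was 0.17 without HF-3 and 0.084 without LF-4. Endothelial markers had -0.26 over 14 (adjusted p = 0.0893), with PECAM1 at -0.76 ± 0.20 and VWF at -0.55 ± 0.25. They passed without HF-2 (median -0.48), LF-2 or LF-4, and had a median of -0.049 without LF-3, -0.11 without HF-3, -0.16 without HF-4 and -0.15 without LF-1. Smooth muscle markers had -0.30 over 7 (adjusted p = 0.384), with MYOCD at 0.94 ± 0.29 and ACTA2 at -0.91 ± 0.29, and passed without LF-4 (median -0.44), while the median was -0.12 without LF-1. ACTA2 passed without LF-4 (-1.14, adjusted p = 0.035). Skeletal muscle markers had -1.56 over 7 (adjusted p = 0.685), with LDB3 at -1.33 ± 0.86 and ACTN2 at -1.56 ± 1.04, and their mean deviation was 3.87 in LF-3, without which the median turned to 1.65, LDB3 was at -0.094 and ACTN2 at 0.53. Without HF-3 these were at -2.45, -2.09 and -2.40. Erythroid markers had 0.21 over 7 (adjusted p = 0.547), -0.11 without HF-2 and 0.56 without LF-1, with EPB42 at 0.42 ± 0.43 and HBAD at 0.39 ± 0.43. EPB42 ranged from 0.095 without HF-1 to 0.68 without HF-3, and HBAD from 0.12 without HF-2 to 0.84 without LF-1. Mesothelial markers had -0.10 over 6, while camera pointed up (adjusted p = 0.97), and 0.43 without LF-1, with WT1 at -0.88 ± 0.33 and TBX18 at 0.71 ± 0.32, or 0.47 without LF-4. Gut and liver markers had -0.20 over 6 (adjusted p = 0.547), from -1.22 without HF-3 to 0.44 without LF-4, with APOA1 as the 1 that fell and VIL1 at 0.78 ± 0.38, or 0.42 without HF-3. Nerve markers had a median of 0.013 and a mean of -0.33 over 3 (adjusted p = 0.777), and -0.23 without LF-1, with SOX10 at -1.03 ± 0.69 and TUBB3 at 0.03 ± 0.28. SOX10 was at -0.55 without LF-1 and -1.56 without HF-2, and TUBB3 ranged from -0.15 without LF-4 to 0.35 without LF-1. The list of conserved Z-linked genes had a median of -0.0062 and a mean of 0.033 over 32, while camera pointed down (adjusted p = 0.384), and 10 members passed adjusted over the list alone, 3 higher and 7 lower. In sums per gene, W and Z copies under 1 symbol, such as those of HINT1, are merged.

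**Figure D4:**
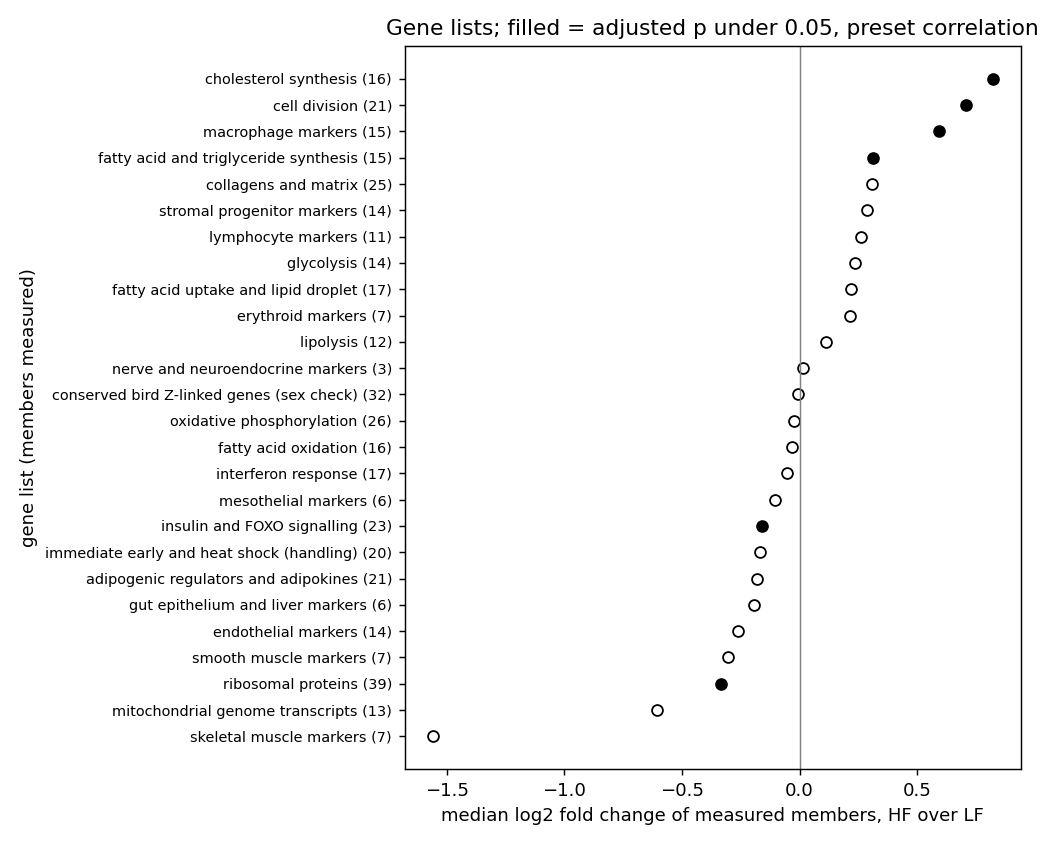
Median log2 fold change of HF over LF for each of 26 gene lists, with the number of measured members in brackets; filled points passed camera's test at an adjusted p under 0.05 with a preset correlation of 0.01. The 4 lists higher in HF lie between 0.31 and 0.82 and the 2 lower at -0.34 and -0.16; with an estimated correlation 0 lists passed.

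Tested as single transcripts, 4 of 23879 mRNA rows passed edgeR's test. A TXNDC5 transcript (XM_027451602.1) held 1500 counts over the HF libraries and 1 over the LF libraries, a ratio of 1630 (exact 95% counting interval 292 to 64400). Its edgeR log2 fold change was 9.96, and 11.67 without LF-1, the library with that count. The sum over TXNDC5 transcripts did not follow it (132.5 ± 24.5 against 137.7 ± 32.8 CPM). An ST14 transcript (XM_027444398.1), of the membrane protease matriptase, held 0 counts in HF and 1389 in LF, at least 426-fold lower in HF. The ST14 sum was 3.25 ± 3.12 against 19.1 ± 2.57 CPM and did not pass (edgeR adjusted p = 0.0741). Transcripts of SCNN1A (XM_027449731.1) and DPYD (XM_027462910.1) were 22.9-fold and 3.35-fold higher in HF. The adjusted p of all 4 was 0.0376. The next transcripts by p were of TMEM200A, FAM192A, PDK4, ANK3, TTBK1 and LRRC28, with edgeR adjusted p between 0.0517 and 0.127. Those of FAM192A (at least 183-fold higher), ANK3 (739), TTBK1 (187) and LRRC28 (262, each at least that many fold lower) were at 0 in a whole group. An unadjusted p under 0.05 was found for 1772 transcripts, where 1194 are expected. DESeq2 called 623 transcripts and limma on log2(FPKM + 1) 16. The count was 35 without LF-4 and 0 or 1 without any other library. Without LF-4, W-described transcripts separate the groups fully (8, 7 and 3 counts in LF-1 to LF-3, at least 1818 in HF). That fit cannot tell sex from fat group. Of the transcripts in the authors' deposited table, 1510 had an unadjusted p under 0.05 and a fold over 2, 786 higher and 724 lower in HF. Only 477 of the 1510 were within the low-count filter used here. Of 38051 rows with reads, 1705 had an unadjusted p under 0.05 there, fewer than expected by chance, and 99 after Benjamini-Hochberg adjustment. All 4 calls had an unadjusted p under 0.05 there, which is not independent, as the libraries are the same.

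No lncRNA passed: 0 of 1247 tested with edgeR, with 60 at an unadjusted p under 0.05, where 62 are expected. DESeq2 called 24 and limma 4, and edgeR called 27 without LF-4. Without LF-4 the groups differ fully in W-described transcripts, so sex and fat group cannot be told apart in that count. The lncRNAs with the smallest p among those higher in HF were XR_217450.4 (8.04 ± 3.35 against 1.42 ± 0.505 CPM), XR_003497816.1 (23.4 ± 8.86 against 2.57 ± 1.94) and XR_003501403.1 (1.68 ± 0.911 against 0.171 ± 0.136). XR_002398923.2 and TCONS_00011831 held 68 and 59 counts in HF and 3 each in LF, ratios of 24.7 (95% counting interval 8.09 to 123) and 21.4 (6.98 to 107). In the other direction were XR_003492471.1 (0.556 ± 0.412 against 8.56 ± 5.54 CPM), XR_003492889.1 (2.70 ± 0.174 against 6.92 ± 1.53) and XR_003500093.1 (0.850 ± 0.468 against 3.44 ± 0.305). TCONS_00014904 and TCONS_00044239 were at 0 in HF, at least 26.3-fold and 23.0-fold lower. The edgeR adjusted p of these 10 lncRNAs lay between 0.114 and 0.426. DESeq2, with 15.3% false calls on simulated lncRNA data, called all 10, and edgeR with no low-count filter called 5.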

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

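The tests on the sex chromosomes, the cholesterol list and the gene sums of transcripts at 0 were chosen after the result was seen; those on splits of the libraries were set before.

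The first pattern is the shift of genes on chromosome Z. In birds females carry ZW and males ZZ, and W-described transcripts were present in the HF libraries and in LF-4. An unequal sex make-up of the groups is a candidate explanation for the Z shift: over all 468 genes on Z the median deviation in LF-4 was -0.0504, nearer to HF than to the other LF libraries. On the 35 Z genes called without LF-4, LF-4 sat at 0.394 of the way from the HF mean to that of LF-1 to LF-3 (95% interval 0.254 to 0.62), which leaves this part open. On 39 called genes off Z the position was 1.07 (0.904 to 1.27), with LF. Both intervals resample genes within 1 library, so they do not cover the spread between samples. The position off Z argues against LF-4 being an HF library under a wrong label, as far as 1 library can show. Sex cannot be told apart from fat group off Z, because LF-4 is the single LF library with W transcripts.

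The second pattern is the higher cholesterol synthesis list in HF. HF-3 held its highest score, but without HF-3 the median was still 0.51. The other HF libraries scored 0.0379 to 0.2524, above all LF libraries (-0.5459 to -0.2397), which argues against HF-3 as the whole cause. Camera's adjusted p without HF-3 was 3.12e-05 at the preset correlation. That setting passed 6 or more lists in 28 of 35 splits of the libraries, so this p adds no support. With all libraries and an estimated correlation camera's adjusted p was 0.716. The score of LF-4 was -0.3411, within the range of the other LF libraries, against a lowest HF score of 0.0379. That gap was smaller than the SD of the HF scores (0.432), but HF-3 at 0.9949 widened this SD. LF-4 is the 1 LF library with W-described transcripts, so sex and fat group cannot be told apart for this list. A link to fat deposition stays a hypothesis, untested beyond the group comparison.

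The third pattern is 38 transcripts at 0 in every library of one group with at least 10 counts in every library of the other. Only 18.9% of the matching gene sums reached an unadjusted p under 0.05, against 15% of all genes, consistent with reads being assigned between similar models of one gene, which had a median of 7 models. The real split gave the most such transcripts: 1 of 35 splits of the libraries reached 38, and the highest other gave 34. A group difference in splicing was not tested.

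Over the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 68 gene sums (highest other 1) or 4 transcripts (highest other 2). A share of 1 in 35 is the smallest that these splits can give. It was not adjusted for the several counts compared over the same splits, so chance is not strictly excluded. The gene sums stood far above every other split, the transcripts only slightly. For lncRNAs all 35 gave 0 or more (highest other 2). For the lists 28 splits gave 6 or more (highest other 13), so chance cannot be excluded for the count of lists.

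Of 256 groups of 4 libraries examined, 20 had a library far from the other 3, where chance gives about 13. LF-3 stood apart in skeletal muscle genes: 12.9 CPM of ACTN2, 13.9 of PFKM and a mean list deviation of 3.87. PFKM was 1.84 CPM in HF-3. LF-4 held 2861 counts of W-described transcripts, 280.1 CPM of APELA, and mean deviations of 0.593 for ribosomal proteins and 0.224 for conserved Z-linked genes. LF-1 had 4.41% mitochondrial counts and 0.0777 CPM of the TXNDC5 transcript, the others 0. LF-2 had 2489 CPM of FASN. SCNN1A was 0.835 CPM in LF-3 and its transcript 0.825. HF-2 had 3.36 CPM of FAM69B, 0.219 of CPLX2, 914 of TIMP3 and 40.03 of DTX3L, and mean deviations of -0.168 for fatty acid uptake and lipid droplets and -0.195 for glycolysis. HF-3 had 82.5 CPM of SPI1.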

How the results depend on the processing

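The W-transcript covariate was chosen after seeing the data; the other alternatives were set before. As LF-4 is the single LF library with W transcripts, this covariate leaves HF against LF-4 alone, which is assumed to vary like the others, so its values do not show whether a result is stable. Scalings kept the counts within 1.5 times. Transcript calls (4) became 623 with DESeq2, 16 with limma, 0 with no filter, 0 with 1 surrogate variable, 28 with the W covariate, 68 summed per gene, and 0 to 35 leaving out a library. Gene calls (68) became 606 with DESeq2, 128 with the W covariate, and 2 to 92 leaving out a library. lncRNA calls (0) became 24 with DESeq2, 4 with limma, 38 with no filter, 1 with the W covariate, and 0 to 27 leaving out a library. Lists past the threshold (6) were 6 with the W covariate, of which 4 were the same (fatty acid and triglyceride synthesis at an adjusted p of 0.0677 and insulin and FOXO signalling at 0.234 did not pass, collagens and stromal progenitors did), and became 0 with an estimated correlation, 1 with fry (insulin and FOXO signalling), and 4 to 11 leaving out a library. Collagens and lymphocyte markers passed with the replicate block and with 1 surrogate variable, and mitochondrial transcripts with the block and with DESeq2's size factors. Leaving out a library leaves fewer samples. Without LF-4 it also leaves W-described transcripts in the HF libraries alone, beyond 8, 7 and 3 counts in LF-1 to LF-3. That fit cannot tell sex from fat group. The cause of the other shifts was not tested.

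No pairing of samples by replicate number was seen. Same-numbered libraries correlated at -0.000759, -0.215, -0.14 and 0.028 in deviations from group means, and each number's best partner was another number. The labels do not state a pairing. With 4 numbers and no correlation above 0.185 between partners, the check could have missed one. With the replicate block the calls were 0 transcripts, 9 genes, 0 lncRNAs and 9 lists.

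Directions turned for genes and lists that did not pass. With the W covariate, log2 fold changes were 0.16 for ACTA2, 1.29 for LDB3, 1.70 for ACTN2, 0.15 for MT-ND6, 0.052 for LPL and 1.58 for ADIPOQ, and list medians were 0.19 for adipogenic regulators, 0.31 for endothelial, 0.54 for smooth muscle, 2.13 for skeletal muscle, 1.74 for mesothelial, 0.13 for handling and 0.15 for mitochondrial transcripts. In that fit camera's direction turned for lipolysis (median 0.073) and nerve (0.0027), whose medians kept their sign. For list: mesothelial markers the median was 0.17 with the replicate block and with 1 surrogate variable, and for list: oxidative phosphorylation 0.022 with the block, with camera's direction unchanged. LPL was 0.018 with upper-quartile scaling, 0.074 with limma and 0.033 with the replicate block. ADIPOQ was 0.0075, 0.11 and 0.18 in the same fits and 0.12 with 1 surrogate variable. The interferon median was 0.016 with 1 surrogate variable, and fry pointed down for mesothelial markers (median -0.10). The cause was not tested.

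Leaving out a library, values ranged from -2.40 to 0.53 for ACTN2, -2.09 to -0.094 for LDB3, -0.15 to 0.35 for TUBB3, -0.20 to 0.018 for FABP4, -0.22 to 0.055 for FOXO1, -0.18 to 0.21 for LPL and -0.30 to 0.46 for ADIPOQ. List medians ranged from 0.012 to 0.14 for lipolysis, -0.13 to 0.043 for fatty acid oxidation, -0.82 to 0.052 for mitochondrial transcripts, -0.13 to 0.068 for oxidative phosphorylation, -0.18 to 0.058 for interferon, -2.45 to 1.65 for skeletal muscle, -0.11 to 0.56 for erythroid, -0.36 to 0.43 for mesothelial, -1.22 to 0.44 for gut and liver, -0.23 to 0.052 for nerve and -0.035 to 0.022 for Z-linked genes. Of the 20 named genes past the threshold, SCNN1A and DPYD passed in all 8 such fits and APOA1 in 0.

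Neighbouring genes were not run, since no lncRNA passed. Of 13220 accessions 9 matched the reference table with their version and 2542 without it. Alternatives meant for tables without counts did not apply. The lncRNA table held 92196 to 175194 counts per library. On lncRNA data simulated at that depth, not scaled as in the main fit, edgeR recovered 0% of 4-fold changes and limma 7%. DESeq2 recovered 43%, and 15.3% of its calls were false. A count of 0 therefore does not show that no lncRNA differs. Depth, replicate number and test were not compared as causes.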

Other observations

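The KEGG pathways were tested after the data were seen. Of 283 pathways on the gene sums, 7 passed camera's test at a preset correlation, 6 higher in HF and 1 lower, and 0 with an estimated correlation (adjusted p = 0.999). Steroid biosynthesis, with 16 genes and a median log2 fold change of 0.75, had an adjusted p of 0.000495, and the phagosome, with 90 genes and a median of 0.22, 0.00703. The lysosome had a median of 0.15 over 96 genes (adjusted p = 0.0216) and antigen processing and presentation 0.34 over 26 (adjusted p = 0.0223). The ribosome was lower, at -0.23 over 105 genes (adjusted p = 0.000367). Other pathways near lists that passed did not pass camera's test at the preset correlation. They included cell cycle (median 0.078, adjusted p = 0.891), FoxO signalling (0.010, adjusted p = 0.899) and insulin signalling (0.052, adjusted p = 0.874). Near fat synthesis, fatty acid metabolism (0.139, adjusted p = 0.514) and glycerolipid metabolism (-0.00655, adjusted p = 0.998) did not pass. Near cholesterol synthesis, terpenoid backbone biosynthesis (0.149, adjusted p = 0.567) and cholesterol metabolism (0.0763, adjusted p = 0.958) did not pass either.

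Other genes past the threshold, chosen after their values were seen, included the taurine transporter SLC6A6 (231 ± 29.5 CPM in HF, 474 ± 35.2 in LF, SD, n = 4) and the angiotensin receptor AGTR2 (32.0 ± 10.9 against 108 ± 20.1), both lower in HF, and the osteogenic factor RUNX2 (3.46 ± 0.610 against 10.2 ± 1.58). FGF2 (158 ± 25.8 against 83.1 ± 14.9 CPM), the macrophage pore protein gene MPEG1 (38.6 ± 4.09 against 17.8 ± 3.29) and the peptide transporter TAP2 (29.96 ± 7.11 against 13.4 ± 1.58) were higher. Their edgeR adjusted p lay between 0.016 and 0.0419.

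The first component of log2 CPM took 28.4% of the variance and put the HF libraries between -47.7 and -3.93 and the LF libraries between 6.98 and 38.3. Transcripts at 0 in LF-1 to LF-3 with at least 10 counts in the other 5 libraries numbered 49, against at most 36 for any other 3 libraries. Of these 49, 16 carried a symbol of the conserved Z-linked list. Among all 21931 transcripts with at least 10 counts in 5 or more libraries, 102 did (Fisher's exact test, two-sided, p = 4.13e-26). Transcripts of the same gene share reads and all come from the same libraries. They are not independent, so that p overstates the evidence.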
